A study of Homo sapiens with 96 samples.

How the data were processed

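RNA sequencing was carried out on 96 libraries of the human cell line A549. Per the labels, the kit was MGIEasy RNA Directional Library Prep, which keeps the strand of each transcript. The sources used here do not say whether the strand entered the counting, so antisense genes and genes overlapping a partner are treated as uncertain. Per the labels, the libraries belong to 2 batches with separate vehicle libraries. The first held 7 groups and 21 libraries (2 extracts at 3 doses, and vehicle), the second 25 groups and 75 libraries (8 ingredients at 3 doses, and vehicle), with 3 libraries per group. The labels number the replicates of each group from 1 to 3 and do not say whether they came from separate cultures.

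The deposited table holds expected counts per gene for 60675 genes, made by the authors. Per the submitters' processing notes, FastQC, Trim Galore, STAR and RSEM 1.3.3 were used with the human build GRCh38 (hg38). Their settings, the annotation release and the handling of reads that match several genes are not given in the sources used here. RSEM shares such reads among the genes they match, so paralogs, pseudogenes and readthrough genes are reported as uncertain. Of the deposited values, 89.2% were whole numbers. No count was found in any library for 17093 genes, and 1847 symbols were carried by more than 1 gene identifier. GC content was taken from GENCODE v29, which may not be the release the authors used.

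The expected counts were rounded to whole numbers. Totals per library ranged from 17.9 to 28.1 M (median 23.2) in the first batch and from 15.7 to 35.6 M (median 23.7) in the second. No pair of replicates held identical values (0 of 96 pairs).

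Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F-test (glmQLFit and glmQLFTest), trimmed mean of M-values (TMM) factors, filterByExpr and Benjamini-Hochberg adjustment over the genes tested in each comparison, with a threshold of 0.05. Every adjusted p given for a gene comes from this test. Unchanged genes alone would put a share of 0.05 of the genes tested under an unadjusted p of 0.05. Each batch was fitted alone with all its groups, without covariates. After filtering, 16854 genes were tested in the first batch and 18324 in the second. TMM factors ranged from 0.911 to 1.04 and from 0.934 to 1.1, residual degrees of freedom were 14 and 50, and the common biological coefficient of variation was 0.0444 and 0.212. Log2 changes are given with their standard error, and CPM (counts scaled to TMM-adjusted library size) as mean ± SD of 3 libraries. The design gave 52 comparisons, 11 in the first batch and 41 in the second. They covered each extract and ingredient against its vehicle per dose, ethanol against water extract at matched dose, highest against lowest dose, and 3 pairs of structurally related ingredients at matched dose. For these pairs, 95% intervals of the log2 difference were computed as well. A fold against a group without counts is given as a lower bound from a floor of 3 counts over the group. With 1 to 3 counts it is given with an exact (Clopper-Pearson) interval, which covers counting error only.

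For 28 gene lists, written with their members before the data were examined, camera (limma 3.58.1) compared the members with all other tested genes at a preset inter-gene correlation of 0.01, and again with the correlation estimated. P-values were adjusted over the 28 lists within a comparison. The Aurora B list follows the title of the series, which names that pathway from these same samples, so its test is not independent evidence.

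A rule fixed at the same time set which genes are named. For each extract at 500 µg/mL against vehicle these are the 8 genes with the largest rise and the 8 with the largest fall in log2 change. They were taken among genes past the threshold, with a mean of at least 1 CPM in 1 of the groups and all 3 treated libraries beyond all 3 vehicle libraries. The same rule gave 5 and 5 genes for ethanol against water extract at 500 µg/mL, 3 and 3 for each ingredient at 10 µM, and 2 and 2 for each related pair at 10 µM. Clone and locus identifiers were passed over. AURKB, INCENP, BIRC5 and CDCA8 are named in every extract comparison, as are up to 4 members with the smallest p from each list past its test. Genes named in 1 comparison may be followed in others. Some genes the rule picked are not reported here.

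Correlations between comparisons that share vehicle libraries were set beside simulations of unchanged groups, because shared controls alone give positive values. Overlaps were set beside those of independent lists, as simulated groups gave almost no calls.

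The test was checked on simulated counts for the real genes and library sizes, with 200 genes changed, 50 at each fold. At 1.25-, 1.5-, 2- and 4-fold it recovered 70, 82, 92 and 100% in a simulation of ethanol extract at 500 µg/mL (16536 genes, 7 false among 179 calls) and 66, 84, 92 and 100% for ethanol against water extract at 100 µg/mL (16541 genes, 7 of 178). It recovered 4, 34, 60 and 94% for oleanolic acid at 10 µM (18000 genes, 2 of 98) and 4, 44, 64 and 96% for gallic acid at 10 against 0.4 µM (18000 genes, 3 of 107).

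The alternatives were DESeq2 size factors within edgeR, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, only the 2 groups of a comparison in the fit, and the mean of the other 7 ingredients as reference. The lists were also tested with an estimated correlation and, for the extracts at 500 µg/mL, with the block. After the data had been seen, 2 alternatives were added for the second batch. These were leaving out 4 libraries with COL1A2 above 10 CPM, and the log2 share of mitochondrially encoded transcripts as a covariate. The labels give no source for the replicate numbers, so their pairing was checked from the deviations of libraries from their group means over genes of at least 10 CPM. Every same-numbered pair correlated above 0.1 in 2 of the 11 comparisons of the first batch and in 7 of the 41 of the second. By this rule alone the numbers were taken to pair the libraries there. These were ethanol extract at 100 µg/mL against vehicle, water extract at 500 against 20 µg/mL, albiflorin at 2 µM against vehicle, and albiflorin, oleanolic acid and paeonol at 10 against 0.4 µM. The others were paeoniflorin against albiflorin at 10 and at 2 µM and hederagenin against oleanolic acid at 10 µM. Pairing stays uncertain, as in some of the second batch a library correlated most with another number.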

Results

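To investigate how Paeoniae Radix, the dried root of the peony used in traditional medicine, alters gene expression in A549 human lung adenocarcinoma cells, transcript levels were measured by RNA sequencing after exposure to whole extracts or to single ingredients. In the first batch, cells received a water extract or an ethanol extract at 500, 100 or 20 µg/mL, or vehicle. In the second, cells received 1 of 8 ingredients at 10, 2 or 0.4 µM, or vehicle. The ingredients were the monoterpene glycosides paeoniflorin and albiflorin, the triterpenes hederagenin and oleanolic acid, the phenolic compounds catechin, gallic acid and paeonol, and benzoic acid. Each of the 32 groups had 3 libraries. The exposure time and the kind of vehicle are not given in the sources used here. Because the labels do not say that replicates were separate cultures, the p-values measure only the spread between these libraries, which may be technical. The title of the series names the Aurora B pathway, whose kinase, with its partners, directs chromosome segregation and cytokinesis.

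The share of mitochondrially encoded transcripts, a sign of RNA quality and library composition, was 13.9 to 18.5% in the vehicle libraries of the first batch and 11.6 to 15.3% in the treated ones. In the second batch it was 11.6 to 12.1% in the vehicle libraries and 0.486 to 15.5% in the treated ones. COL1A2 was at 496 to 595 CPM in 4 libraries of the second batch (replicate 2 of catechin at 10 and 2 µM, replicate 1 of gallic acid at 2 and 0.4 µM). It was at most at 0.899 CPM in the other 71.

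With ethanol extract at 500 µg/mL against vehicle, hypoxia-responsive genes and p53 targets rose. Genes of mitosis, heat shock chaperones and genes of ribosome biogenesis fell. NDRG1, a hypoxia-responsive gene, rose from 68.4 ± 1.1 to 683 ± 16 CPM (log2 3.32 ± 0.05, n = 3 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 5.82e-24). DLGAP5, which encodes a spindle protein, fell by 4.19 ± 0.06 on the log2 scale, from 78.6 ± 5.2 to 4.29 ± 0.32 CPM (edgeR adjusted p = 5.82e-24). AURKB, the Aurora B kinase, fell from 92.6 ± 1.2 to 49.2 ± 1.1 CPM, a log2 change of -0.91 ± 0.04 (edgeR adjusted p = 1.89e-15).

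The other members of the chromosomal passenger complex, which holds AURKB at the centromere and midzone, also fell. INCENP changed by -0.58 ± 0.05, BIRC5 by -0.72 ± 0.04 and CDCA8 by -0.83 ± 0.05 on the log2 scale, with edgeR adjusted p between 6.54e-13 and 6.43e-10 for INCENP and CDCA8 and of 1.34e-13 for BIRC5. Of the 37 Aurora B pathway genes tested, 30 fell, 4 rose and 3 did not pass, the same counts as adjusted over the list alone (median log2 -0.58, camera adjusted p = 4.66e-11). The list follows the title of the series and is not independent evidence. BUB1, a spindle checkpoint kinase, went from 113 ± 2.1 to 20.3 ± 1.1 CPM (log2 -2.47 ± 0.05) and AURKA from 152 ± 5.6 to 41.9 ± 0.77 (-1.86 ± 0.04). VIM, the intermediate filament vimentin, is also in the list and rose from 981 ± 38 to 1960 ± 31 CPM. Of the 40 genes of mitosis and G2/M, 36 fell and 3 rose (median -0.80, camera adjusted p = 1.15e-29), again the same adjusted over the list alone. HMMR changed by -2.92 ± 0.05 and CCNB1, the cyclin of mitotic entry, by -1.79 ± 0.05. Among 40 genes of DNA replication and G1/S, 27 fell and 8 rose (median -0.24, camera adjusted p = 0.00615), and this call was lost with an adjusted p = 0.171 with an estimated correlation.

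Other lists rose at the same dose. Of 28 hypoxia genes, 27 rose and 0 fell (median 1.54, camera adjusted p = 7.86e-56), among them the glucose transporter SLC2A1 (1.78 ± 0.04) and the prolyl hydroxylase EGLN3 (3.10 ± 0.06). Of 25 p53 targets, 23 rose and 2 fell (median 0.78, camera adjusted p = 6.58e-10), with BBC3 at 1.97 ± 0.08 and MDM2 at 0.92 ± 0.04. In the ATF4 and amino acid response list 17 of 25 genes rose and 4 fell (median 0.63, camera adjusted p = 7.29e-08), led by STC2 (15.1 ± 2.1 to 164 ± 3.9 CPM, log2 3.45 ± 0.08) and the asparagine synthetase ASNS (0.93 ± 0.04). The NF-kB list rose in 13 of 18 genes and fell in 3 (median 0.63, camera adjusted p = 6.59e-07), with BIRC3 at 1.75 ± 0.06 and the chemokine CXCL8 at 3.76 ± 0.17. Immediate early and ERK targets rose in 15 of 21 genes (median 0.58, camera adjusted p = 1.14e-05). YAP targets rose in 14 of 20 genes and fell in 5 (camera adjusted p = 2.19e-05), led by IGFBP3 (172 ± 13 to 1040 ± 20 CPM), while TGFB2, which this list shares with the TGF-beta list, fell by 1.41 ± 0.05. Autophagy and lysosome genes rose in 15 of 22 and fell in 4 (camera adjusted p = 0.00018). Metallothioneins rose in 3 of 4 genes (camera adjusted p = 0.00162), MT1X by 2.44 ± 0.07. Adjusted over the list alone, the counts of all these lists were unchanged.

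Heat shock genes fell in 17 of 17 cases (median -1.15, camera adjusted p = 1.95e-27), the cochaperone FKBP4 by 1.39 ± 0.03. HSPA1A fell from 368 ± 7.8 to 50.6 ± 3 CPM and its near-identical paralog HSPA1B from 228 ± 17 to 50.7 ± 3.3, so their separate values are uncertain. Ribosome biogenesis genes fell in 21 of 23 cases (median -0.75, camera adjusted p = 8.95e-12), NOP56 by 1.32 ± 0.04. NRF2 targets fell in 15 of 27 genes and rose in 5 (16 and 5 adjusted over the list alone; camera adjusted p = 0.0115), including the heme oxygenase HMOX1 (131 ± 5.3 to 59.4 ± 3.1 CPM, -1.14 ± 0.05), but the adjusted p = 0.118 with an estimated correlation. Further calls were lost with an estimated correlation. These were aryl hydrocarbon receptor targets (3 rose and 3 fell of 7, 4 and 3 adjusted over the list alone, camera adjusted p = 0.0404, then 0.0809), cholesterol synthesis (14 rose and 3 fell of 25, 0.025, then 0.249), fatty acid synthesis (5 rose and 8 fell of 14, 0.025, then 0.0898) and interferon response (13 rose and 2 fell of 20, 0.0404, then 0.069). The same held for apoptosis regulators (16 rose and 8 fell of 25, 0.00117, then 0.069), TGF-beta and mesenchymal genes (5 rose and 12 fell of 24, 0.0347, then 0.29), cytosolic ribosomal proteins (35 rose and 1 fell of 45, 0.00587, then 0.382) and the nuclear-encoded respiratory chain (2 rose and 23 fell of 33, 0.0139, then 0.501). Lists not past their test were iron handling (4 rose and 6 fell of 12, camera adjusted p = 0.537), LXR targets (4 and 1 of 8, 0.087), mitochondrially encoded genes (0 and 12 of 13, 0.0852), airway and alveolar epithelium (5 and 7 of 15, 0.306) and markers of other cell types (2 and 1 of 6, 0.704). The unfolded protein response list was not past it either (6 rose and 9 fell of 18, 7 and 9 adjusted over the list alone, 0.537), and its median of -0.07 and mean of 0.10 differed in sign.

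In all, 11654 of 16854 genes passed the edgeR test, 5851 higher and 5803 lower, and 2732 of them changed at least 2-fold. Both TMM and DESeq2 scaling give relative changes, so a shift of all RNA would not show. By size, MYOD1, a regulator of muscle differentiation, led the rises, with 23.3 ± 0.95 CPM against no count in vehicle, at least 521-fold higher. TCHH (log2 5.55 ± 0.32), NEURL1 (5.46 ± 0.49) and PCK1, which encodes an enzyme of gluconeogenesis (1.23 ± 0.35 CPM against 2 counts in vehicle, a ratio of 41.9 with an exact interval of 11.3 to 351), followed. NCF1 (2.05 ± 0.34 CPM), GOLGA6C (1.83 ± 0.36 CPM) and the pseudogenes SLC2A3P1 and CDCA4P4 (at least 68.9-fold and 38.2-fold higher) share sequence with relatives and are uncertain. Among the falls, COLQ had no count in treated cells against 1.14 ± 0.085 CPM, at least 27.7-fold lower. SDS, a serine dehydratase, changed by -4.96 ± 0.15, the transporter SLCO1B3 by -3.72 ± 0.16, LBP by -3.71 ± 0.32, R3HDML by -3.65 ± 0.39, the plasminogen gene PLG by -3.60 ± 0.40 and POLN by -3.57 ± 0.30.

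**Figure D1:**
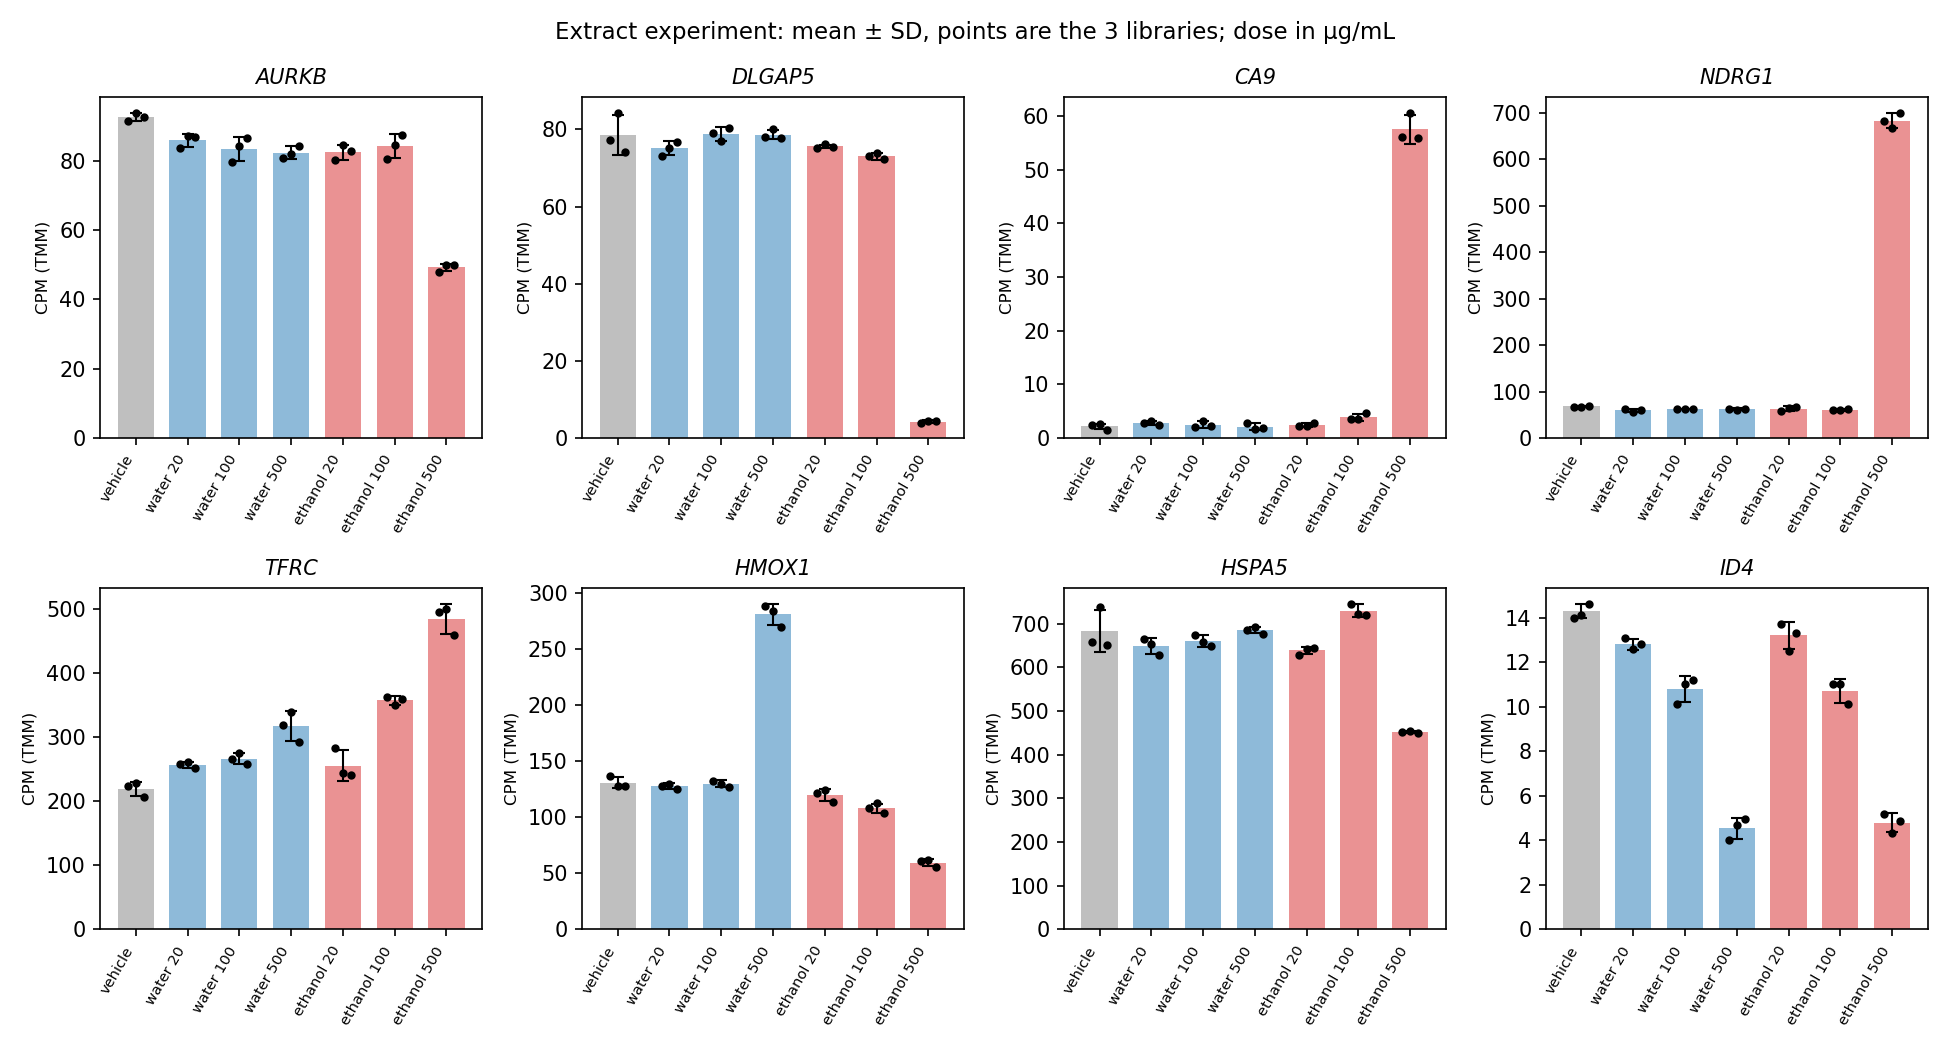
CPM (TMM-scaled) of 8 genes in vehicle and in water and ethanol extract at 20, 100 and 500 µg/mL, as mean and SD (bars) with 3 libraries (points). With ethanol extract at 500 µg/mL DLGAP5 was at 4.29 CPM against 78.6 in vehicle.

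The water extract at 500 µg/mL was then compared with vehicle. Iron handling genes, NRF2 targets and aryl hydrocarbon receptor targets rose, and heat shock, TGF-beta and metallothionein genes fell. HMOX1, which degrades heme, rose from 131 ± 5.3 to 281 ± 9.2 CPM (log2 1.10 ± 0.04, n = 3 per group, edgeR adjusted p = 5.86e-14). CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose from 73.4 ± 3.3 to 120 ± 7.6 CPM (0.71 ± 0.05, edgeR adjusted p = 1.36e-09). AURKB was slightly lower, at 82.3 ± 1.8 against 92.6 ± 1.2 CPM (-0.17 ± 0.04, edgeR adjusted p = 0.00279), while INCENP (0.00 ± 0.05, 0.977), BIRC5 (0.02 ± 0.04, 0.791) and CDCA8 (0.04 ± 0.05, 0.591) did not pass.

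Of 12 iron handling genes, 6 rose and 1 fell (camera adjusted p = 6.07e-10), with the transferrin receptor TFRC at 0.53 ± 0.06 and FBXL5 at 0.47 ± 0.06. Of 27 NRF2 targets, 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 2.06e-07). HMOX1 belongs to both lists. Aryl hydrocarbon receptor targets rose in 4 of 7 genes (camera adjusted p = 7.09e-06), with CYP1A1 at 1.38 ± 0.32 and TIPARP at 0.44 ± 0.05. Heat shock genes fell in 13 of 17 cases (14 adjusted over the list alone; camera adjusted p = 1.08e-11). Of 24 TGF-beta and mesenchymal genes, 12 fell and 3 rose (16 and 3 adjusted over the list alone; camera adjusted p = 1.33e-07), among them SNAI1 (-0.67 ± 0.08). Metallothioneins fell in 2 of 4 genes (camera adjusted p = 0.000708). Immediate early genes fell in 7 of 21 (9 adjusted over the list alone; camera adjusted p = 0.00336). These 7 lists also passed with an estimated correlation, the last at an adjusted p = 0.0498.

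Another 7 lists passed only with the preset correlation. Of 13 mitochondrially encoded genes, 12 fell (median -0.53, camera adjusted p = 5.95e-09, and adjusted p = 0.185 with an estimated correlation). Ribosome biogenesis genes fell in 11 of 23 (12 fell and 1 rose adjusted over the list alone; 0.000234, then 0.185). Mitosis genes fell in 9 and rose in 4 of 40 (10 and 4 adjusted over the list alone; 0.0473, then 0.278). The remaining lists were p53 targets (6 rose and 1 fell of 25, 0.0394, then 0.268), the unfolded protein response (7 rose and 2 fell of 18, 8 and 3 adjusted over the list alone, 0.0394, then 0.209), cholesterol synthesis (7 rose and 1 fell of 25, 8 and 1 adjusted over the list alone, 0.0274, then 0.278) and interferon response (3 rose of 20, 0.0473, then 0.0937). The Aurora B list did not pass (8 fell and 5 rose of 37, median -0.05, camera adjusted p = 0.142), nor did hypoxia genes (3 rose and 7 fell of 28, 0.265).

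The water extract at 500 µg/mL gave 3553 genes past the edgeR test, 1635 higher and 1918 lower, and 133 changed at least 2-fold. The largest falls were in CRYAB, a small heat shock protein (log2 -2.20 ± 0.21, 4.34 ± 0.83 to 0.954 ± 0.29 CPM), and in the transcription regulators ID4 (-1.65 ± 0.08) and ATOH8 (-1.41 ± 0.10), followed by NCCRP1 (-1.19 ± 0.26) and LDLRAD2 (-1.16 ± 0.31). CGB8 (-1.48 ± 0.35), which has close paralogs, and the antisense genes CERS6-AS1 (-1.49 ± 0.31) and RALY-AS1 (-1.45 ± 0.28) are uncertain. So are the 8 largest rises. These were the readthrough genes INO80B-WBP1 (at least 54.3-fold) and HSPE1-MOB4 (2.91 ± 0.51), the pseudogenes SLC2A3P1 (at least 32.6-fold), SMG1P4 (1.73 ± 0.46) and SNX18P3 (1.23 ± 0.15), the multicopy signal recognition particle RNAs Metazoa_SRP (2.97 ± 0.72) and RN7SL1 (2.26 ± 0.66), and the antisense gene AATBC (1.27 ± 0.27).

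Ethanol and water extract were then compared directly at matched dose. At 500 µg/mL the ethanol extract gave higher hypoxia genes and lower mitotic genes, and HMOX1 was at 59.4 ± 3.1 CPM against 281 ± 9.2 with the water extract (log2 -2.24 ± 0.05, n = 3 per group, edgeR adjusted p = 2.53e-21). All 4 members of the passenger complex were lower with ethanol extract, AURKB by -0.74 ± 0.04, INCENP by -0.59 ± 0.05, BIRC5 by -0.74 ± 0.04 and CDCA8 by -0.87 ± 0.05 (edgeR adjusted p from 9.89e-14 for BIRC5 to 6.34e-10 for INCENP). Of 37 Aurora B genes, 29 were lower and 4 higher (camera adjusted p = 1.73e-10), and of 40 mitosis genes 35 were lower and 2 higher (36 and 2 adjusted over the list alone; 3.24e-29). All 28 hypoxia genes were higher (1.02e-63). NRF2 targets were lower in 19 of 27 genes and higher in 5 (1.83e-05), and heat shock genes lower in 16 of 17 (17 adjusted over the list alone; 2.28e-20). Higher with ethanol extract were p53 targets (21 of 25, 2 lower, 8.56e-09), immediate early genes (19 of 21, 1 lower, 2.21e-08), YAP targets (15 of 20, 3 lower, 5.86e-06), NF-kB genes (12 of 18, 2 lower, 3.35e-06) and metallothioneins (3 of 4, 1.31e-05). These lists passed with an estimated correlation too, at adjusted p of at most 0.0164. In all, 11134 genes passed the edgeR test, 5514 higher and 5620 lower with ethanol extract. The named extremes were MYOD1 (1 count over the water libraries), CXCR4 (1.4 ± 0.1 CPM against no count, at least 30.9-fold higher), GOLGA6C, WNT7A and IL2RG (1 or 2 counts over the water libraries) upwards. Downwards they were COLQ (at least 28.6-fold lower), SDS (-4.37 ± 0.16), DLGAP5 (-4.19 ± 0.06), LBP (-4.04 ± 0.30) and CAMK2A (-3.64 ± 0.38).

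At 100 µg/mL the extracts differed in 299 genes by edgeR, 156 higher and 143 lower with ethanol extract. The unfolded protein response, which raises chaperones of the endoplasmic reticulum, was higher with ethanol extract in 10 of 18 genes (15 adjusted over the list alone; camera adjusted p = 8.12e-29). TGF-beta genes were lower in 9 of 24 (10 adjusted over the list alone; 5.43e-18). Fatty acid synthesis genes were lower in 3 of 14 (7 lower and 1 higher adjusted over the list alone; 0.000115), and NF-kB genes higher in 2 of 18 (0.0034). These 4 lists also passed with an estimated correlation. The ATF4 list was higher in 5 of 25 genes (8.09e-07) but had an adjusted p = 0.0618 with an estimated correlation. The Aurora B list was lower in 1 gene of 37, BUB1 (-0.15 ± 0.04), with a camera adjusted p = 0.00114, and an adjusted p = 0.166 with an estimated correlation. AURKB (0.01 ± 0.04, edgeR adjusted p = 0.943), INCENP (0.02 ± 0.05, 0.933), BIRC5 (-0.09 ± 0.04, 0.319) and CDCA8 (-0.02 ± 0.05, 0.939) did not pass. The count fell to between 121 (without ethanol extract 100 µg/mL replicate 3) and 187 (without its replicate 1) when any 1 of the 6 libraries was left out. With the replicate block, in libraries not taken as paired, it was 451. At 20 µg/mL 0 genes passed in edgeR and 0 in DESeq2, with 735 at an unadjusted p under 0.05 and 88 past the edgeR test without the filter on low counts. AURKB differed by -0.06 ± 0.04 (edgeR adjusted p = 0.982), INCENP by 0.00 ± 0.05, BIRC5 by -0.11 ± 0.04 and CDCA8 by -0.12 ± 0.05. The Aurora B list was lower (camera adjusted p = 0.0467) with 0 genes past the test, and had an adjusted p = 0.655 with an estimated correlation.

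Against vehicle, the ethanol extract at 100 µg/mL raised genes of the unfolded protein response and of the amino acid response, and heat shock and TGF-beta genes fell. Of 18 unfolded protein response genes, 13 rose (14 adjusted over the list alone; camera adjusted p = 2.69e-12). The ATF4 list rose in 12 of 25 genes (13 adjusted over the list alone; 8.39e-09). TGF-beta genes fell in 12 of 24 (15 fell and 1 rose adjusted over the list alone; 2.39e-14), as did heat shock genes in 11 of 17 (12 alone; 7.86e-11) and immediate early genes in 8 of 21 with 1 risen (9 and 2 alone, 0.000358). These lists passed with an estimated correlation. NRF2 targets (11 rose and 1 fell of 27, 13 and 2 adjusted over the list alone, 0.00108, then an adjusted p = 0.0963 with an estimated correlation), Aurora B genes (8 fell and 1 rose of 37, 9 and 1 alone, 0.0242, then 0.262), mitochondrially encoded genes (11 fell of 13, 12 alone, median -0.44, 3.46e-07, then 0.262), ribosome biogenesis (10 fell and 1 rose of 23, 11 and 1 alone, 0.000241, then 0.205) and metallothioneins (1 fell of 4, 0.0356, then 0.0963) did not keep their call. AURKB was at 84.2 ± 3.4 CPM (-0.14 ± 0.04, edgeR adjusted p = 0.0147), a call lost without ethanol extract 100 µg/mL replicate 1, without the filter and with only both groups in the fit, and INCENP, BIRC5 and CDCA8 had edgeR adjusted p of 0.572 to 0.694. This comparison gave 2947 genes in edgeR, and 1908 without ethanol extract 100 µg/mL replicate 1. At 20 µg/mL the ethanol extract gave 1255 genes. This count was 108 with only both groups in the fit, 603 without its replicate 1, and above that but still moved without vehicle replicate 1 or 3. AURKB was at 82.4 ± 2.2 CPM (-0.17 ± 0.04, edgeR adjusted p = 0.00881), lost without ethanol extract 20 µg/mL replicate 1 and with only both groups in the fit. INCENP changed by 0.05 ± 0.05, BIRC5 by -0.04 ± 0.04 and CDCA8 by -0.01 ± 0.05.

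The water extract gave 2116 genes at 100 µg/mL and 1602 at 20 µg/mL. They fell as far as 1005 without water extract 100 µg/mL replicate 2 and 703 without water extract 20 µg/mL replicate 1, and less far without replicate 1 of the first, 2 of the second or vehicle replicate 1 or 3. With only both groups in the fit they were 1400 and 803. HMOX1 was at 130 ± 2.9 and 128 ± 2.4 CPM at 100 and 20 µg/mL, against 131 ± 5.3 in vehicle. AURKB was at 83.4 ± 3.5 CPM at 100 µg/mL (-0.15 ± 0.04, edgeR adjusted p = 0.0135) and 85.9 ± 1.9 at 20 µg/mL (-0.11 ± 0.04, 0.0748). The call at 100 µg/mL was lost without water extract 100 µg/mL replicate 1, without the filter and with only both groups in the fit. INCENP, BIRC5 and CDCA8 changed by 0.03 ± 0.05, 0.06 ± 0.04 and 0.06 ± 0.05 at 100 µg/mL and by 0.05 ± 0.05, 0.07 ± 0.04 and 0.11 ± 0.05 at 20 µg/mL. Heat shock genes fell in 9 of 17 at 100 µg/mL (11 adjusted over the list alone; camera adjusted p = 1.46e-08) and in 8 at 20 µg/mL (9 alone, 3.02e-08), with adjusted p = 0.0653 and 0.0749 with an estimated correlation. With ethanol extract at 20 µg/mL they fell in 6 (7 adjusted over the list alone; 2.76e-08, then 0.0747). Mitochondrially encoded genes fell in 11, 12 and 7 of 13 in these 3 comparisons (12 in each adjusted over the list alone; 9.22e-10, 1.28e-13 and 5.66e-09), with adjusted p = 0.443, 0.382 and 0.429 with an estimated correlation.

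Comparing the highest with the lowest dose removed the vehicle libraries from the contrast. With the water extract, HMOX1 (281 ± 9.2 against 128 ± 2.4 CPM, log2 1.14 ± 0.04, n = 3 per group, edgeR adjusted p = 3.13e-14), CYP1B1 (0.65 ± 0.05), TIPARP (0.45 ± 0.05), FBXL5 (0.42 ± 0.06) and TFRC (0.31 ± 0.06) were higher at 500 than at 20 µg/mL. Iron handling genes rose in 5 of 12 (6 adjusted over the list alone; camera adjusted p = 4.56e-20), aryl hydrocarbon receptor targets in 2 of 7 (3 adjusted over the list alone; 3.2e-10) and NRF2 targets in 5 of 27 with 1 lower (6 and 1 adjusted over the list alone; 7.61e-07). Unfolded protein response genes rose in 3 of 18 (6 adjusted over the list alone; 0.000133), NF-kB genes in 3 with 1 lower of 18 (9 and 2 adjusted over the list alone; 0.000584), and metallothioneins fell in 2 of 4 (3 adjusted over the list alone; 0.00113). All 6 lists passed with an estimated correlation. The Aurora B list had 1 lower gene of 37 (camera adjusted p = 0.0556, and 0.0393 with the replicate block), and AURKB (-0.06 ± 0.04, edgeR adjusted p = 0.521), INCENP (-0.04 ± 0.05), BIRC5 (-0.05 ± 0.04) and CDCA8 (-0.07 ± 0.05) did not pass. In all 346 genes passed, and between 158 (without water extract 500 µg/mL replicate 2) and 202 (without water extract 20 µg/mL replicate 3) when a library was left out, except for 255 without water extract 500 µg/mL replicate 3. With the ethanol extract, 11377 genes differed between 500 and 20 µg/mL by edgeR, 5729 higher and 5648 lower. Mitosis genes fell in 36 of 40 with 2 risen (camera adjusted p = 2.55e-28), Aurora B genes in 30 of 37 with 4 risen (2.78e-10), and hypoxia genes rose in 28 of 28 (4.99e-59). AURKB changed by -0.74 ± 0.04, INCENP by -0.63 ± 0.05, BIRC5 by -0.68 ± 0.04 and CDCA8 by -0.82 ± 0.05.

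**Figure D2:**
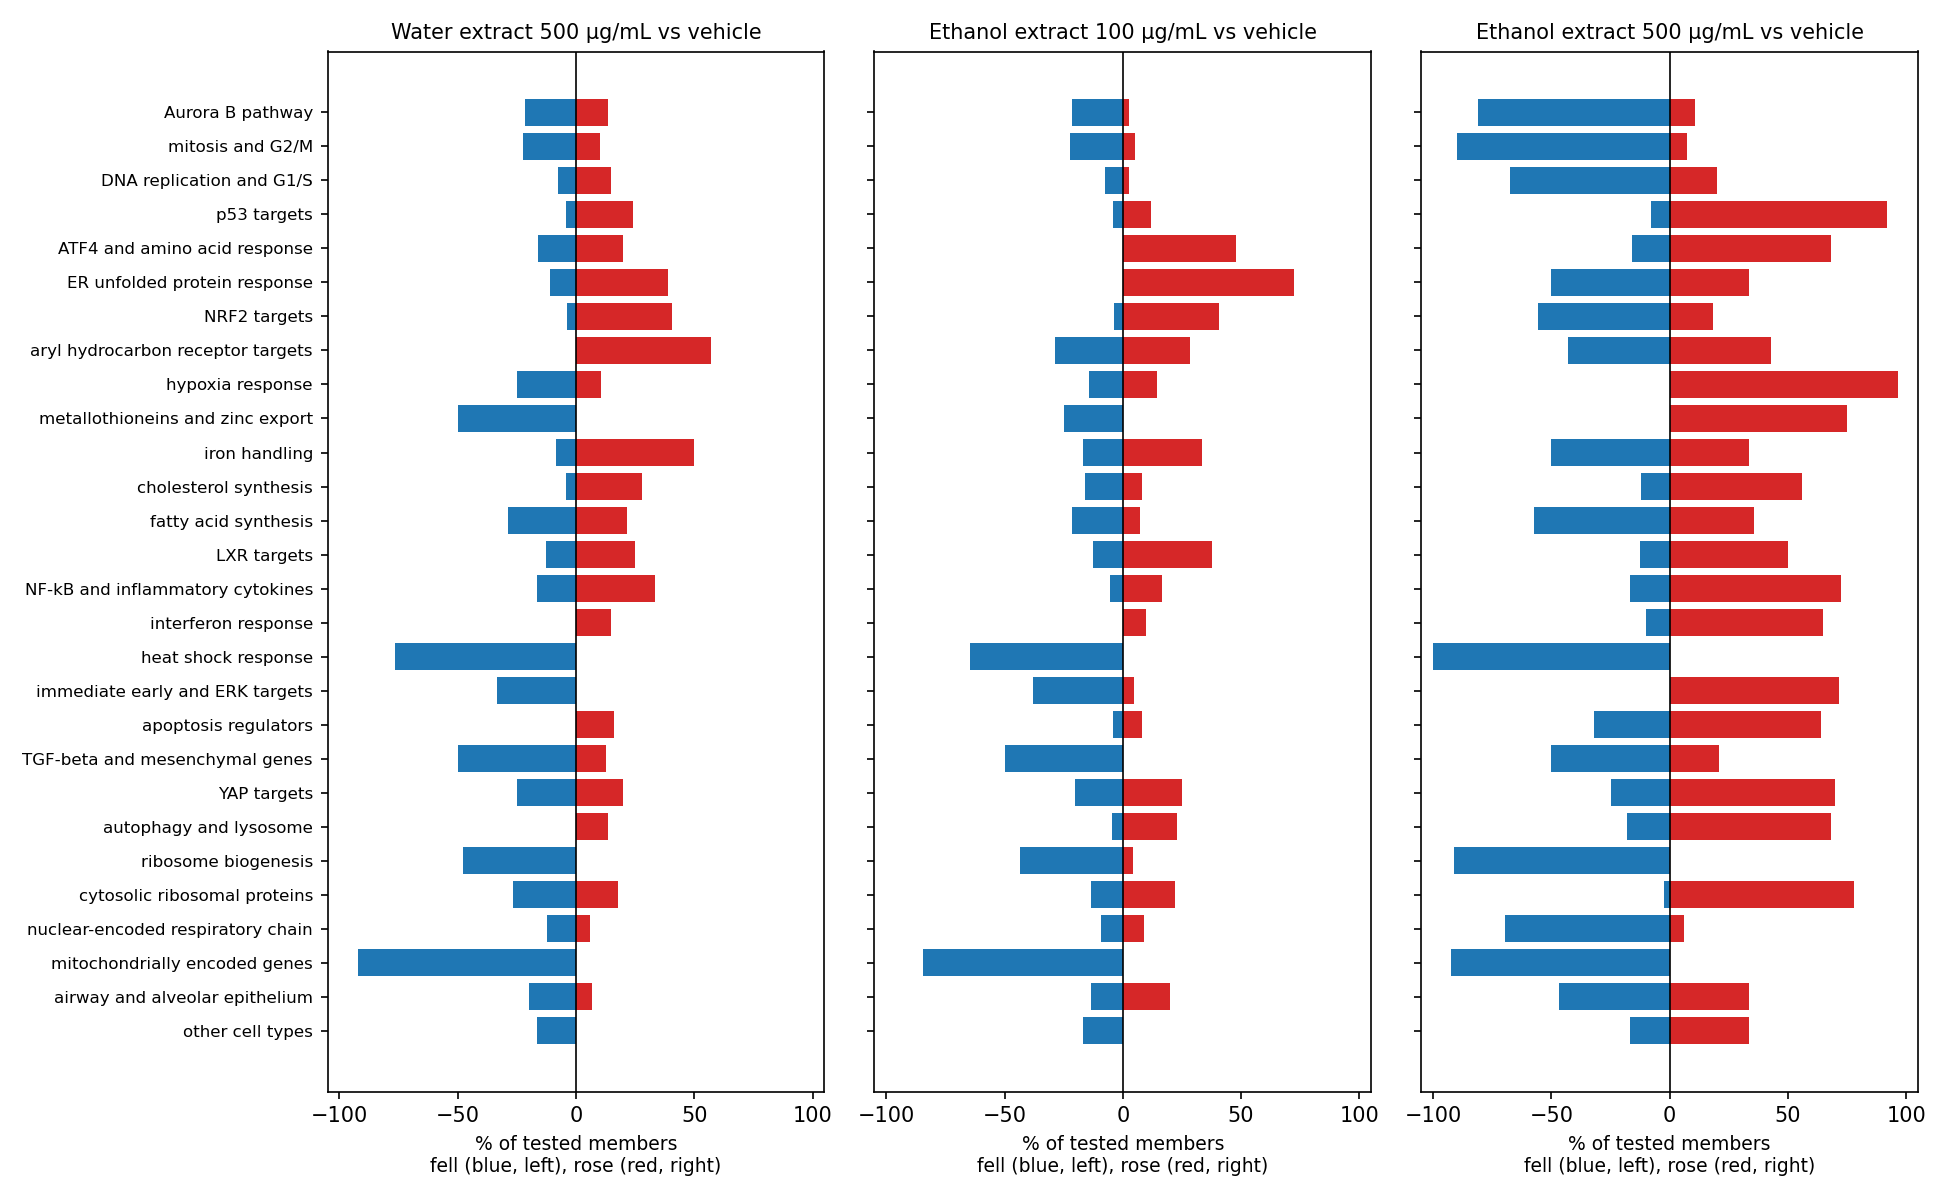
Percent of tested members that fell (left) or rose (right) in each of 28 gene lists against vehicle, for water extract at 500 µg/mL and ethanol extract at 100 and 500 µg/mL. With ethanol extract at 500 µg/mL 27 of 28 hypoxia genes rose and 36 of 40 mitosis genes fell.

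Water and ethanol extract at 500 µg/mL both raised 932 genes and both lowered 1269, where independent lists of these sizes would share 568 and 660. Another 744 genes moved in opposite directions, HMOX1 among them. The log2 changes correlated across genes at r = 0.342 with a covariance of 0.135. Simulated groups gave a mean r of 0.499 (0.432 to 0.560 over 20 simulations) and a covariance of 0.0284. Genes are not independent replicates, and part of any excess may come from the shared vehicle libraries, which are too few to split.

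Against vehicle, genes of the ATF4 and amino acid response rose with both triterpenes at 10 µM, oleanolic acid and hederagenin. Genes of cholesterol synthesis fell. CHAC1, a glutathione-degrading enzyme induced by ATF4, rose from 2.36 ± 0.062 to 20 ± 2.2 CPM with oleanolic acid (log2 3.08 ± 0.30, n = 3 per group, edgeR adjusted p = 4.44e-11) and to 15.4 ± 2.1 with hederagenin (2.70 ± 0.30, edgeR adjusted p = 3.98e-09). STC2 rose from 12.4 ± 0.44 CPM to 86.6 ± 3 and 74.6 ± 6.7 (2.81 ± 0.24 and 2.59 ± 0.23). The ATF4 list rose in 20 of 25 genes with oleanolic acid (21 rose and 1 fell adjusted over the list alone; median 1.13, camera adjusted p = 8.04e-64) and in 18 with hederagenin (20 adjusted over the list alone; 9.91e-49). Cholesterol synthesis genes fell in 11 and 10 of 25 (15 and 14 adjusted over the list alone; 1.13e-13 and 7.65e-13). Heat shock genes fell in 8 and 2 of 17 (14 and 9 adjusted over the list alone; 2.47e-20 and 7.2e-08). Hypoxia genes fell in 2 and 3 of 28 (7 and 4 adjusted over the list alone; 0.00149 and 7.35e-05). These lists passed with an estimated correlation.

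With oleanolic acid at 10 µM, mitosis genes fell in 11 of 40 (25 adjusted over the list alone; median -0.40, camera adjusted p = 6.95e-17). Aurora B genes fell in 7 of 37 (11 adjusted over the list alone; 4.15e-07), INCENP to 64.7 ± 5.3 CPM (-0.70 ± 0.14, edgeR adjusted p = 0.000793). Replication genes fell in 4 of 40 (7 fell and 1 rose adjusted over the list alone; 6.5e-06). All 3 lists passed with an estimated correlation. With hederagenin the mitosis list fell with 1 gene past the test (2.47e-07, then an adjusted p = 0.0554 with an estimated correlation) and the Aurora B list with 0 (0.00267, then 0.307). Beyond the lists, oleanolic acid raised LAMP3 (2.72 ± 0.66) and lowered the iodide transporter SLC5A5 (-1.71 ± 0.23), NEB (-1.70 ± 0.36) and GRHL3 (-1.47 ± 0.24), and hederagenin lowered GRHL3 (-1.14 ± 0.23), ZC3H6 (-1.11 ± 0.27) and HYAL1 (-1.03 ± 0.19). The pseudogene RPL12P28 (2.80 ± 0.69 with hederagenin) is uncertain. The mitochondrial share was 11.2, 10.3 and 2.97% in the 3 oleanolic acid libraries and 7.73, 7.61 and 2.54% in the hederagenin ones, against 11.6 to 12.1% in vehicle. In edgeR, 815 genes passed for oleanolic acid (473 higher and 342 lower) and 444 for hederagenin (285 and 159). The counts were 2363 and 1520 with the log2 mitochondrial share as a covariate, a setting chosen after seeing the data, 3737 and 2901 with only both groups in the fit, 337 and 168 without the filter, and for hederagenin 677 in DESeq2 and 198 against the other 7 ingredients. The lowest counts with 1 library left out were 445 for oleanolic acid (vehicle replicate 1) and 222 for hederagenin (its replicate 3), and leaving out any 1 vehicle library or replicate 2 or 3 of the compound moved the count.

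Gallic acid at 10 µM raised chaperones of the endoplasmic reticulum and HMOX1. HMOX1 rose from 122 ± 2.5 to 313 ± 22 CPM (log2 1.36 ± 0.15, n = 3 per group, edgeR adjusted p = 1.84e-08). Of 18 unfolded protein response genes, 12 rose (12 rose and 1 fell adjusted over the list alone; median 0.72, camera adjusted p = 1.98e-07), with MANF at 1.08 ± 0.18 and HYOU1 at 0.90 ± 0.16. YAP targets fell in 7 of 20 genes (10 fell and 1 rose adjusted over the list alone; 2.72e-07), AMOTL2 by 1.12 ± 0.13. Both lists passed with an estimated correlation. YAP targets fell against vehicle with other ingredients too. Against benzoic acid at 10 µM the list had a camera adjusted p = 0.0132 (0.283 with an estimated correlation) and AMOTL2 differed by -0.37 ± 0.13 (edgeR adjusted p = 0.0665), and against gallic acid at 0.4 µM the list had 0.0161 (then 0.245). The mitochondrial share was 1.44, 15.5 and 2.07% in gallic acid replicates 1, 2 and 3. MANF was at 109, 53.7 and 72.9 CPM in these libraries, against 35.8 to 38.5 in vehicle. Other lists passed only with the preset correlation. These were ribosomal proteins (14 rose of 45, 17 adjusted over the list alone, 0.00027, then an adjusted p = 0.542 with an estimated correlation), ribosome biogenesis (11 rose of 23, 12 rose and 1 fell alone, 0.00147, then 0.411), the nuclear-encoded respiratory chain (8 rose of 33, 16 alone, 0.000698, then 0.542) and TGF-beta genes (6 fell of 24, 7 alone, 0.000257, then 0.183). NRF2 targets (7 rose of 27, 7 rose and 1 fell alone, 0.00482, then 0.183), autophagy genes (8 rose of 23, 8 and 1 alone, 0.0496, then 0.271), mitosis genes (2 rose and 2 fell of 40, median -0.19, 0.0238, then 0.514), replication genes (9 rose and 1 fell of 40, 13 and 1 alone, 0.0443, then 0.411) and mitochondrially encoded genes (0 past the test, median -0.85, 0.00892, then 0.551) did the same. By size, HMGN5 (2.40 ± 0.59) rose and NSUN7 (-1.71 ± 0.28) fell. CERS6-AS1 (antisense, 3.73 ± 0.69), RPL12P28 (pseudogene, 3.32 ± 0.69), ANKRD10-IT1 (intronic, -2.17 ± 0.71) and MEIS3P2 (pseudogene, -1.74 ± 0.33) are uncertain. The edgeR count of 2469 genes (1560 higher and 909 lower) rested on single libraries. It was 7312 without gallic acid replicate 2, 136 without replicate 1, and between these but under the full count without replicate 3 or any 1 vehicle library, and 0 genes passed with only both groups in the edgeR fit, with 1088 without the filter and 3132 in DESeq2.

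For the other 5 ingredients few genes passed at 10 µM with spread pooled over groups, so counts do not rank them. Albiflorin gave 7 genes in edgeR, benzoic acid 5, catechin 12, paeoniflorin 35 and paeonol 23, with 476, 449, 2172, 1173 and 3824 at an unadjusted p under 0.05, so smaller changes were not excluded. CLK1, a kinase of splicing factors, rose with each of them, from 15.3 ± 2 CPM to 26.8 ± 0.84 with albiflorin (log2 0.80 ± 0.10, n = 3 per group, edgeR adjusted p = 6.45e-07) and to 33.6 ± 4.4 with paeoniflorin (1.13 ± 0.10, edgeR adjusted p = 5.48e-12), with changes of 0.76 ± 0.10 to 1.08 ± 0.10 for the other 3. The transcription factor KLF2 fell by 0.78 ± 0.15 with catechin to 1.05 ± 0.15 with paeoniflorin, and AMOTL2 and CTGF, both YAP targets, fell in each case, AMOTL2 by 0.60 ± 0.13 with paeonol to 0.83 ± 0.13 with catechin. YAP targets fell as a list with albiflorin (2 of 20, 4 adjusted over the list alone, camera adjusted p = 4.8e-10), benzoic acid (2, 4 alone, 6.9e-11), catechin (3, 5 alone, 2.98e-07) and paeoniflorin (3, 8 alone, 1.44e-09), and these held with an estimated correlation. With paeonol the call (2 fell, 5 fell and 1 rose alone, 0.00258) had an adjusted p = 0.341 with an estimated correlation. Genes named besides were MAT2A (0.31 ± 0.06) and ZNF627 (0.57 ± 0.11) with albiflorin, AXIN2 (0.98 ± 0.17), FGB (0.45 ± 0.09) and PRKD2 (-0.72 ± 0.16) with catechin, and AXIN2 (0.82 ± 0.17), IL6R (0.61 ± 0.13), LRP2BP (-0.99 ± 0.22) and HSPA1B (-0.88 ± 0.14, with a paralog) with paeoniflorin. With paeonol they were DNASE1 (-0.65 ± 0.14), KLF6 (-0.62 ± 0.10) and the antisense or host transcripts SPACA6P-AS (1.43 ± 0.32) and RPARP-AS1 (0.77 ± 0.17), which are uncertain. Replication genes rose with paeoniflorin (2 of 40, 3 adjusted over the list alone, camera adjusted p = 7.16e-07, and 0.00806 with an estimated correlation). All 8 ingredients at 10 µM raised CLK1 (mean 0.97, against 1.02 at 0.4 µM) and lowered KLF6 (-0.54 against -0.57). Against the mean of the other 7 ingredients, CLK1 changed by -0.19 with albiflorin and -0.24 with benzoic acid, and MAT2A by -0.07 with albiflorin. With that reference the rises of CLK1 with the other 3 no longer passed. Nor did the falls of KLF2 with all 5, of AMOTL2 with albiflorin, benzoic acid and catechin and of CTGF with albiflorin and benzoic acid. Over the 8 ingredients the mean changes at 10 and 0.4 µM were -0.77 and -0.93 for KLF2, -0.62 and -0.67 for AMOTL2 and -0.57 and -0.59 for CTGF. The YAP list did not pass between 10 and 0.4 µM in any of the 5 (camera adjusted p of 0.681 to 0.97). These changes thus depend on the vehicle as reference. Without vehicle replicate 1 the counts were 3, 2, 4, 11 and 3, with only both groups in the fit 1442, 468, 1192, 67 and 0, in DESeq2 14, 16, 103, 78 and 119, and without the filter 3, 3, 5, 6 and 3, and paeonol gave 355 without its own replicate 1.

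At 2 and 0.4 µM, catechin gave 1476 and 854 genes in edgeR, hederagenin 10 and 559, gallic acid 112 and 13, oleanolic acid 59 and 33, paeoniflorin 42 and 25, paeonol 16 and 51, albiflorin 7 and 7, and benzoic acid 4 and 6. Without vehicle replicate 1 each of these 16 counts fell more than 1.5-fold. The mitochondrially encoded list had a median of -1.87 with catechin at 2 µM and -1.86 at 0.4 µM, with 0 of 13 genes past the test. Catechin at 2 µM gave 57 genes with the mitochondrial covariate, 13 without vehicle replicate 3, 3567 without catechin 2 µM replicate 3, more than the full count without its replicate 2, and 4237 without the 4 libraries with COL1A2. Catechin at 0.4 µM gave 900 with the covariate, 43 without vehicle replicate 1, 473 without its own replicate 1 and 6052 with only both groups in the fit. Gallic acid at 2 µM gave 7 without vehicle replicate 1, 2968 without its replicate 3 and 13 without the 4 libraries, and paeonol at 0.4 µM 3 without vehicle replicate 1 and 375 without its replicate 3. Hederagenin at 0.4 µM gave 510 with the covariate, 4641 without its replicate 3, 17 without vehicle replicate 1, and 2 against the other 7 ingredients, and 0 genes passed with only both groups in the edgeR fit (1537 in DESeq2). With oleanolic acid at 2 µM the ATF4 list still rose in 5 of 25 genes (15 adjusted over the list alone; camera adjusted p = 2.01e-23, and 6.51e-09 with an estimated correlation), heat shock genes fell in 4 of 17 (6 alone; 1.07e-14) and the cholesterol list fell with 0 genes past the test (2.93e-06, and 0.00151 with an estimated correlation). For the immediate early list the median and mean differed in sign with albiflorin at 2 µM (-0.17 and 0.01) and catechin at 10 µM (-0.08 and 0.55).

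Between highest and lowest dose, oleanolic acid differed in 453 genes, hederagenin in 192 and gallic acid in 102 by edgeR. The ATF4 list rose with dose in 17 of 25 genes for oleanolic acid (21 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.59e-80) and 15 for hederagenin (20 alone; 9.86e-58), and cholesterol genes fell in 9 and 7 of 25 (12 and 10 alone; 7.06e-15 and 7.46e-14). Replication genes fell in 9 and 2 of 40 (12 and 13 alone; 1.07e-15 and 3.72e-12). With oleanolic acid, mitosis genes (5 of 40, 15 alone, 1.96e-15) and Aurora B genes (4 of 37, 11 alone, 6.87e-08) fell, and NF-kB genes (5 of 18, 9 rose and 1 fell alone, 4.53e-09), p53 targets (2 of 25, 4 alone, 0.000265) and YAP targets (6 of 20, 7 rose and 1 fell alone, 0.000137) rose. With gallic acid the unfolded protein response rose in 6 of 18 genes (11 alone; 3.64e-09), and the TGF-beta list fell with 0 genes past the test (10 alone; 9.02e-07). All these lists passed with an estimated correlation. The mitochondrially encoded list with oleanolic acid had a camera adjusted p = 0.0463, and 0.0532 with the replicate block. The counts for oleanolic acid, hederagenin and gallic acid were 1371, 788 and 447 with the mitochondrial covariate, 1226, 4 and 0 with only both groups in the edgeR fit, and 207, 78 and 22 without the filter. Gallic acid gave 21 without its 10 µM replicate 1 and 1878 without replicate 2, hederagenin 96 and 484 without its 0.4 µM replicates 2 and 3, and oleanolic acid 278 without its 10 µM replicate 3. In the other 5 ingredients 0 genes passed in edgeR, with 108 (albiflorin), 128 (benzoic acid), 875 (catechin), 225 (paeoniflorin) and 236 (paeonol) at an unadjusted p under 0.05 and 3, 9, 12, 8 and 5 in DESeq2.

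**Figure D3:**
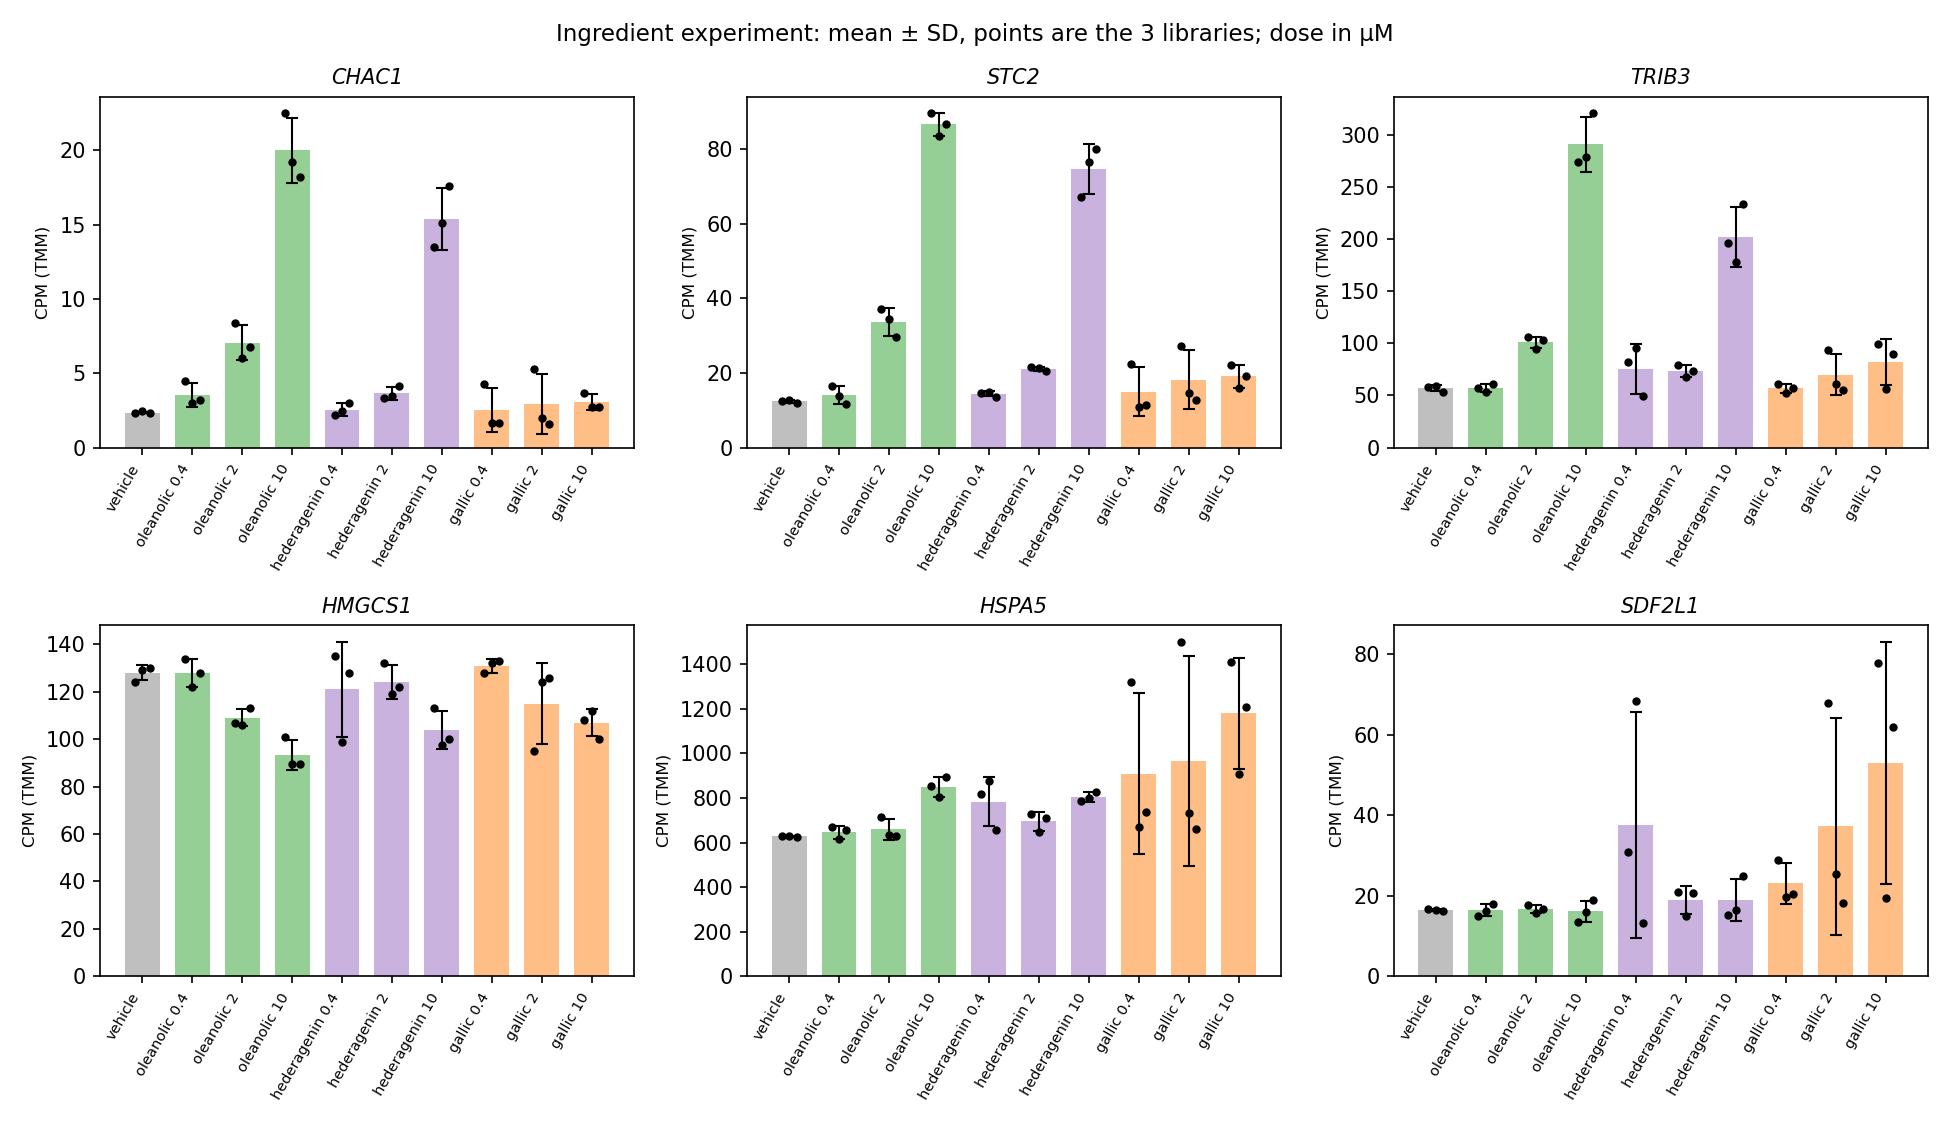
CPM (TMM-scaled) of 6 genes in vehicle and in oleanolic acid, hederagenin and gallic acid at 0.4, 2 and 10 µM, as mean and SD (bars) with 3 libraries (points). STC2 was at 86.6 CPM with oleanolic acid at 10 µM, against 12.4 in vehicle.

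Structurally related ingredients were compared at matched doses. The 95% interval had a median half-width of 0.46 on the log2 scale over 18324 genes. It rests on spread pooled over groups and is too narrow for noisy groups. Each pair crosses sets of label codes, so structure and code set cannot be told apart. Paeoniflorin and albiflorin are isomers. Between them 0 genes passed in edgeR at 10, 2 or 0.4 µM, with 602, 1152 and 456 at an unadjusted p under 0.05 and 14, 9 and 7 in DESeq2. Of the lists, 4, 5 and 3 passed with the preset correlation and 0 with an estimated one, without a gene past the test. Mitochondrially encoded genes were lower with paeoniflorin at 10 and 2 µM (median -0.70 in both, camera adjusted p = 0.00273 and 0.00181, then 0.86 and 0.756), and ribosomal proteins higher at 0.4 µM (0.25, 8.72e-11, then 0.494). Replication and respiratory chain genes were higher at all 3 doses, mitosis genes lower at 10 µM, and iron handling genes lower and ribosome biogenesis genes higher at 2 µM. CLK1 differed by 0.32 ± 0.10 at 10 µM (interval 0.13 to 0.52, edgeR adjusted p = 0.965) and KLF2 by -0.12 ± 0.15 (-0.43 to 0.19). The interval lay within 1 log2 unit of no difference for 13424 genes at 10 µM (73.3%), 12563 at 2 µM and 13723 at 0.4 µM. Larger differences were not excluded for the rest.

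Hederagenin has 1 hydroxyl group more than oleanolic acid. At 10 µM they differed in 2 genes by edgeR, the fibrinogen gene FGB (214 ± 16 CPM with hederagenin against 147 ± 12, log2 0.54 ± 0.09, interval 0.35 to 0.73, edgeR adjusted p = 0.00737) and DUSP5 (49.8 ± 1.1 against 71.7 ± 4.8, -0.53 ± 0.10, interval -0.72 to -0.33, edgeR adjusted p = 0.0155). The ATF4 list was lower with hederagenin (median -0.18, camera adjusted p = 5.44e-09, and 0.000478 with an estimated correlation) with 0 genes past the test and 1 lower adjusted over the list alone. CHAC1 differed by -0.38 ± 0.27 (-0.92 to 0.17) and STC2 by -0.22 ± 0.22 (-0.65 to 0.22). Mitosis genes (median 0.16, 4.59e-09) and replication genes (0.14, 1.51e-08) were higher with hederagenin, as were heat shock genes (0.21, 1.22e-12, 6 adjusted over the list alone), and p53 targets (-0.10, 0.00206), NF-kB genes (-0.17, 0.00037) and immediate early genes (-0.15, 3.67e-05) were lower, all with an estimated correlation too. At 2 µM the ATF4 list was again lower (-0.23, 2.14e-11). At 2 and 0.4 µM 0 genes passed in edgeR, with 346 and 3211 at an unadjusted p under 0.05 and 3 and 9 in DESeq2, and 2006 genes passed at 0.4 µM without hederagenin replicate 3. The interval lay within 1 log2 unit of no difference for 75.6% of genes at 10 µM. The 2 genes did not both pass without hederagenin replicate 2 or 3 or any 1 oleanolic acid library (0 or 1 genes), without the filter (0 genes) or with only both groups in the edgeR fit (0 genes), and 20 passed with the mitochondrial covariate and 6 in DESeq2.

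Gallic acid has 3 hydroxyl groups that benzoic acid lacks, and another code set. At 10 µM they differed in 1594 genes, 1053 higher and 541 lower with gallic acid. HMOX1 was at 313 ± 22 CPM with gallic acid against 123 ± 5.9 (log2 1.35 ± 0.15, n = 3 per group, edgeR adjusted p = 4.13e-08). The unfolded protein response was higher in 12 of 18 genes (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.63e-09), and no other list passed with an estimated correlation (0.00218 for this list). MANF differed by 1.10 ± 0.18 (interval 0.73 to 1.46 with pooled spread). CALY (2.50 ± 0.59), NSUN7 (-1.43 ± 0.29) and the pseudogene MEIS3P2 (-1.46 ± 0.33) were named by size. At 2 and 0.4 µM 0 genes passed in edgeR, with 1551 and 873 at an unadjusted p under 0.05 and 4 and 14 in DESeq2. The count at 10 µM was 7130 without gallic acid replicate 2, 56 without its replicate 1, and between 56 and the full count without its replicate 3 or any 1 benzoic acid library, 0 with only both groups in the edgeR fit, 522 without the filter, 882 with the mitochondrial covariate and 2400 without the 4 libraries with COL1A2.

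**Figure D4:**
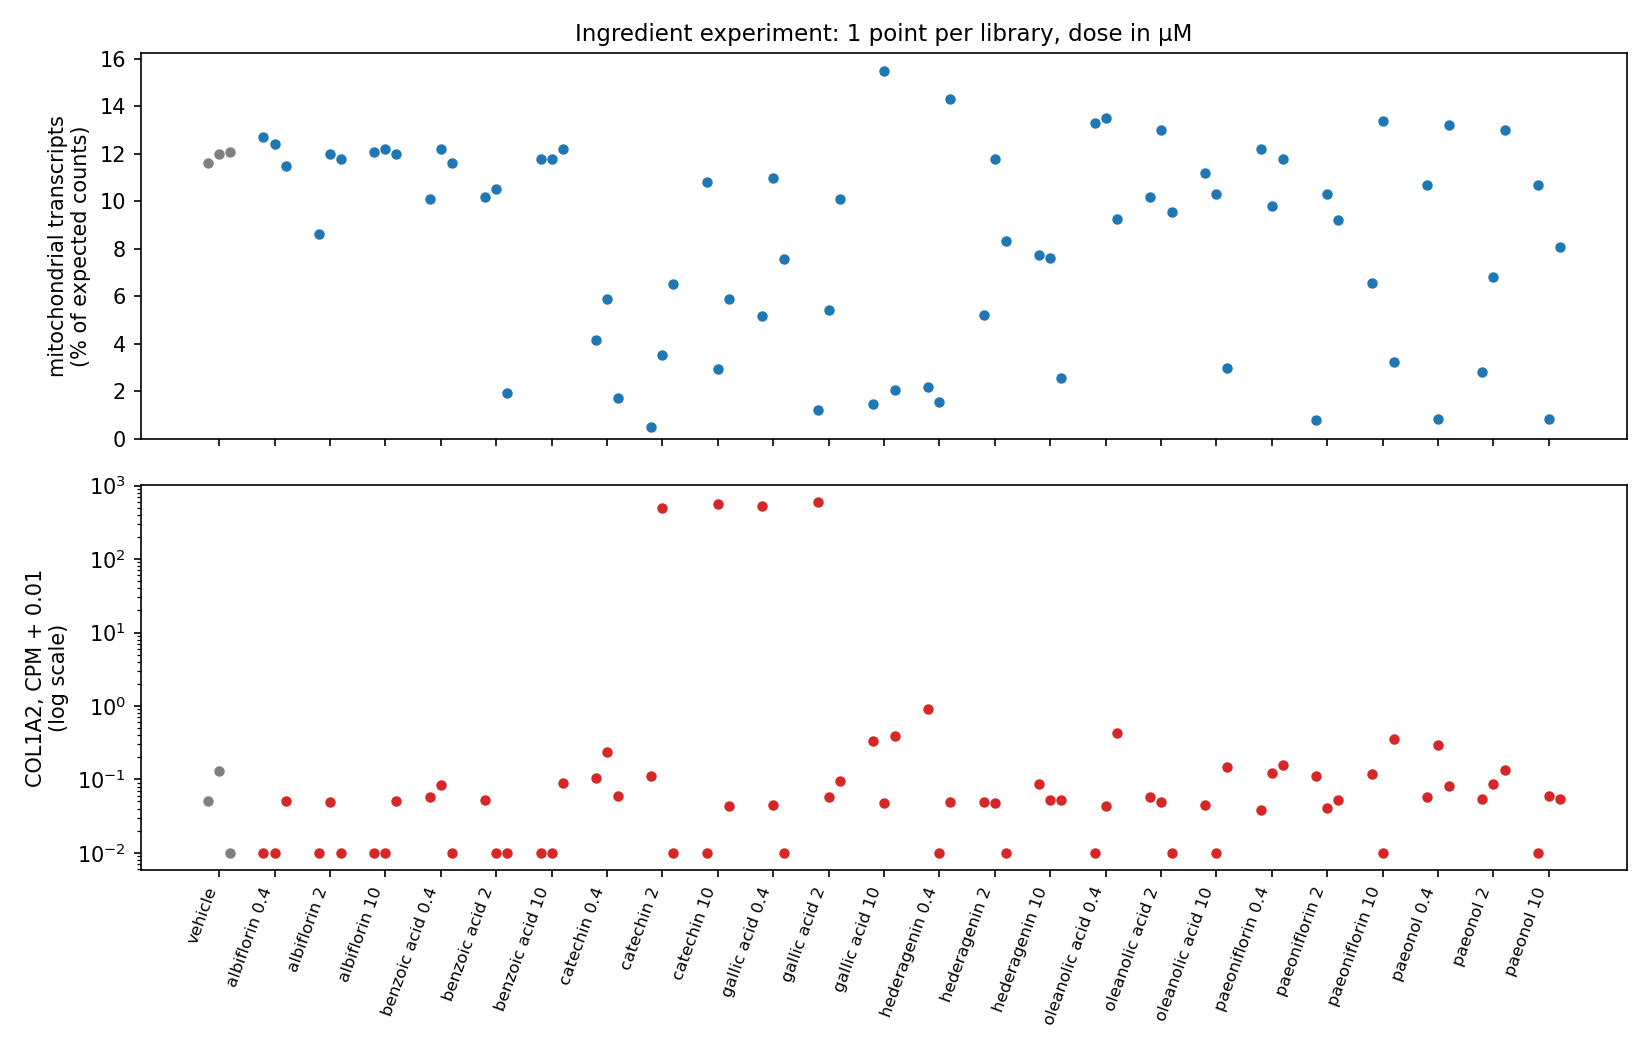
Mitochondrial transcripts in percent of expected counts (top) and COL1A2 in CPM plus 0.01 on a log scale (bottom) in the 75 libraries of the second batch by group, 1 point per library. The share ran from 0.486 to 15.5% in treated libraries, and COL1A2 stood out in 4.

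Across the 28 pairs of ingredients at 10 µM, log2 changes against the shared vehicle correlated across genes at a median r of 0.502 (0.247 to 0.791) with a median covariance of 0.214. Unchanged groups against the same vehicle libraries gave a mean r of 0.505 (0.445 to 0.573 over 8 simulations) with a covariance of 0.154. The highest r was that of gallic acid and paeonol, with a covariance of 0.525. None of these values was corrected for the mitochondrial share. For hederagenin and oleanolic acid r was 0.707 and the covariance 0.276. Both raised 227 genes and lowered 112, where independent lists without a shared vehicle would share 7.36 and 2.97. Between the extracts at 500 µg/mL and the ingredients at 10 µM, whose doses are not matched and which share no libraries, the 16 correlations over 16633 genes lay between -0.137 and 0.004.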

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

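Of the tests below, those of the treatment, the fibroblasts, the code sets, GC content and a handling difference alike in both batches were chosen only after the result was seen.

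Several results stood out because groups differed under the same contrast. Ethanol and water extract differed in 11134 genes at 500 µg/mL and 299 at 100 µg/mL, hederagenin and oleanolic acid at 10 µM in 2, and gallic and benzoic acid at 10 µM in 1594. The extracts at 500 µg/mL moved 744 genes in opposite directions, against 932 both raised and 1269 both lowered. The number from independent lists was not computed. HMOX1 differed between the extracts by -2.24 on the log2 scale. The other genes singled out between the extracts were MYOD1 (10.15), CXCR4 (8.03), GOLGA6C (6.48), WNT7A (5.96), IL2RG (5.88), COLQ (-7.78), SDS (-4.37), DLGAP5 (-4.19), LBP (-4.04) and CAMK2A (-3.64). For MYOD1, CXCR4, GOLGA6C, WNT7A, IL2RG and COLQ 1 group held 0 to 3 counts, so the fitted log2 value depends on the prior count and is no bound.

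The vehicle libraries stood apart from treated libraries even at the lowest doses. Shifts against vehicle at the lowest dose correlated between the batches at r = -0.132 over 16633 genes (-0.195 at 10 CPM or more), which argues against 1 handling difference alike in both batches, an explanation worded after the value was seen. The bound fixed before, r below 0.1 against handling of any kind, was met too. It was wrong for handling in general, as batches, if made separately, need not shift the same genes. Vehicles of both batches share a code set of their own, so handling and treatment cannot be told apart. A response shared by all 8 ingredients stays open as well, since the 20 genes called in at least 4 of them moved by a median of 0.005 between 0.4 and 10 µM against 0.542 from vehicle, and a response already full at 0.4 µM would look the same.

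In the 4 libraries high in COL1A2 (codes 715, 716, 721 and 722) PRRX1 was at 27.4 to 35.9 and RN7SK at 1080 to 1360 CPM. RUNX2, INHBA, WNT7A and TMEFF2 were higher too (under 1 CPM elsewhere). Treatment is argued against, as COL1A2 was at most 0.1 CPM in the other 8 libraries of these groups. RNA of stromal fibroblasts stays open. Of 16 fibroblast genes 3 were higher in all 4, the others under 1 CPM there (DCN up to 0.961) or higher elsewhere. Reads from libraries that hold RNA without a poly(A) tail stay open, with 1 of the 4 detected ones higher in all 4, too few to decide. RNA of other cells was not tested.

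The mitochondrial share of the second batch followed the first component of all other genes (r = 0.970 over 75 libraries, 37.2% of the variance). Within code sets treatment groups showed no difference (permutation p = 0.935), and 66.4% of the variance lay within groups. Code sets differed (permutation p = 0.003, 18.7% of the variance, medians of 11.8, 5.3, 7.67 and 10.2%). Each holds its own ingredients, so set and ingredient cannot be told apart. The component's gene loadings followed GC content (r = -0.392), so a library bias in GC content may contribute to it, and what gave rise to that bias was not tested.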

How the results depend on the processing

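The alternatives that leave out the 4 libraries with COL1A2 or add the mitochondrial covariate were chosen after seeing the data. In the first batch, counts of genes past the test stayed within 1.5 times in 11 of 11 in DESeq2, 11 of 11 with DESeq2 size factors, 10 of 11 without the filter on low counts, 8 of 11 with only the 2 groups in the fit and 10 of 11 with the replicate block. In the second they stayed so in 5 of 41 in DESeq2, 41 of 41 with DESeq2 size factors, 12 of 41 without the filter on low counts, 12 of 41 with only the 2 groups in the fit, 38 of 41 with the replicate block, 2 of 24 against the other 7 ingredients, 32 of 41 without the 4 libraries and 13 of 41 with the covariate. There, chi-square per degree of freedom between replicates ran from 2.04 to 437. Genes under about 1 CPM rest on few counts. For each value below that moved, the cause was not tested. Of the named genes past the test, 20 of 20 passed under every setting with ethanol extract at 500 µg/mL, 14 of 14 between the extracts at 500 µg/mL, 12 of 17 with water extract at 500 µg/mL, 5 of 6 with oleanolic acid and 3 of 6 with hederagenin at 10 µM, and 0 with each other ingredient.

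With only the 2 groups in the fit, the counts that moved over 1.5 times, at 10, 2 and 0.4 µM where 3 are given, were 1442, 65, 471 (albiflorin), 468, 0, 305 (benzoic acid), 1192, 6052 (catechin 10, 0.4 µM), 0, 0 (gallic acid 10, 2 µM), 2901, 2359, 0 (hederagenin) and 3737, 1744, 2027 (oleanolic acid). Next came 67, 0, 54 (paeoniflorin), 0, 4, 0 (paeonol), 1, 0, 4, 1226 (albiflorin, gallic acid, hederagenin, oleanolic acid 10 against 0.4 µM), 1 (paeoniflorin against albiflorin 10 µM), 0 (hederagenin against oleanolic acid 10 µM) and 0 (gallic acid against benzoic acid 10 µM). Then came 1400, 803 (water extract 100, 20 µg/mL) and 108 (ethanol extract 20 µg/mL). In DESeq2 they were 14, 15, 18 (albiflorin), 16, 18, 19 (benzoic acid), 103, 3032, 1322 (catechin), 663, 61 (gallic acid 2, 0.4 µM), 677, 63, 1537 (hederagenin) and 110, 74 (oleanolic acid 2, 0.4 µM). Next came 78, 103, 66 (paeoniflorin), 119, 46, 146 (paeonol), 3, 9, 12, 218, 8, 5 (albiflorin, benzoic acid, catechin, gallic acid, paeoniflorin, paeonol 10 against 0.4 µM), 14, 9, 7 (paeoniflorin against albiflorin), 6, 3, 9 (hederagenin against oleanolic acid) and 4, 14 (gallic acid against benzoic acid 2, 0.4 µM). Without the filter on low counts they were 3, 3, 3 (albiflorin), 3, 2, 2 (benzoic acid), 5, 74, 203 (catechin), 1088, 26, 5 (gallic acid), 168, 5, 84 (hederagenin) and 337, 14, 8 (oleanolic acid). Next came 6, 8, 9 (paeoniflorin), 3, 3, 12 (paeonol), 22, 78, 207 (gallic acid, hederagenin, oleanolic acid 10 against 0.4 µM), 0 (hederagenin against oleanolic acid 10 µM), 522 (gallic acid against benzoic acid 10 µM) and 88 (ethanol against water extract 20 µg/mL). Against the mean of the other 7 ingredients they were 25, 0, 0 (albiflorin), 16, 0, 0 (benzoic acid), 340, 338, 225 (catechin), 248, 250 (gallic acid 2, 0.4 µM), 198, 1, 2 (hederagenin) and 36, 0 (oleanolic acid 2, 0.4 µM). Next came 11, 0, 0 (paeoniflorin) and 35, 0, 19 (paeonol). Without the 4 libraries with COL1A2 they were 7 (benzoic acid 2 µM), 4237 (catechin 2 µM), 13 (gallic acid 2 µM), 33, 1321 (hederagenin 2, 0.4 µM), 50 (oleanolic acid 0.4 µM) and 43 (paeoniflorin 0.4 µM). Next came 36 (paeonol 10 µM) and 2400 (gallic acid against benzoic acid 10 µM). With the log2 mitochondrial share as covariate they were 18, 17, 20 (albiflorin), 19, 16, 18 (benzoic acid), 133, 57 (catechin 10, 2 µM), 192, 89 (gallic acid 2, 0.4 µM), 1520, 191 (hederagenin 10, 2 µM) and 2363, 302, 155 (oleanolic acid). Next came 155, 101, 173 (paeoniflorin), 63, 120, 115 (paeonol), 447, 788, 1371 (gallic acid, hederagenin, oleanolic acid 10 against 0.4 µM), 1 (paeoniflorin against albiflorin 2 µM), 20, 3 (hederagenin against oleanolic acid 10, 2 µM) and 882 (gallic acid against benzoic acid 10 µM).

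At 10 µM against the other 7 ingredients CLK1 and MAT2A turned to -0.19 and -0.07 with albiflorin, and CLK1 to -0.24 with benzoic acid. With an estimated correlation the Aurora B list had camera adjusted p of 0.262 (ethanol extract 100 µg/mL), 0.166 (ethanol against water extract 100 µg/mL) and 0.655 (20 µg/mL). Over genes of at least 10 CPM the correlations of changes against vehicle at 10 µM that moved were, with albiflorin, 0.778 (benzoic acid), 0.095 (catechin), 0.061 (gallic acid), 0.217 (hederagenin), 0.201 (oleanolic acid), 0.354 (paeoniflorin) and 0.066 (paeonol). With benzoic acid they were 0.145 (gallic acid), 0.286 (oleanolic acid) and 0.128 (paeonol), with catechin 0.656 (gallic acid), 0.664 (paeoniflorin) and 0.623 (paeonol), with gallic acid 0.784 (paeoniflorin) and 0.926 (paeonol), with hederagenin 0.876 (oleanolic acid) and 0.789 (paeoniflorin), and between paeoniflorin and paeonol 0.795.

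With the replicate number as a block, in comparisons not taken as paired, the counts moved to 28 (hederagenin 2 µM), 67 (paeoniflorin 2 µM), 51 (paeonol 10 µM) and 451 (ethanol against water extract 100 µg/mL). In the same way the camera adjusted p went from 0.0473 to 0.0534 for interferon response with water extract at 500 µg/mL, and with ethanol extract at 500 µg/mL from 0.0404 to 0.0766 for aryl hydrocarbon receptor targets, from 0.0404 to 0.0686 for interferon response and from 0.0852 to 0.0125 for mitochondrially encoded genes. MAT2A with albiflorin at 10 µM (0.31) no longer passed with the block, and AURKB with water extract at 20 µg/mL (-0.11) did. Beyond these and 2 lists in comparisons that the numbers pair, it changed no other call among the named genes and lists tested with it. Counts of genes stayed within 1.5 times elsewhere, but rose from 3553 to 4139, from 2116 to 2851 and from 1602 to 2391 (water extract 500, 100, 20 µg/mL), from 1255 to 1873 (ethanol extract 20 µg/mL) and, where the numbers pair, from 2947 to 3629 (ethanol extract 100 µg/mL) and from 346 to 507 (water extract 500 against 20 µg/mL).

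Libraries were left out in turn, and the replicate numbers of those that gave the lowest and the highest count follow in brackets, at 10, 2 and 0.4 µM where 3 ranges are given. With groups of 2 fitted on the spread pooled over all groups, counts ranged from 1908 to 2949 for ethanol extract 100 µg/mL (its 1, vehicle 2), 121 to 187 for ethanol against water extract 100 µg/mL (ethanol extract 3, ethanol extract 1), 603 to 1426 for ethanol extract 20 µg/mL (its 1, its 3), 0 to 1 for ethanol against water extract 20 µg/mL (ethanol extract 1, water extract 2) and 1005 to 2399 for water extract 100 µg/mL (its 2, vehicle 2). They ranged from 703 to 1924 for water extract 20 µg/mL (its 1, vehicle 2), 158 to 255 for water extract 500 against 20 µg/mL (500 µg/mL 2, 500 µg/mL 3), 1 to 5, 3 to 5 and 2 to 6 for albiflorin (its 3, vehicle 2; vehicle 1, vehicle 2; vehicle 1, vehicle 3). Ranges further were 2 to 6, 2 to 4 and 1 to 6 for benzoic acid (vehicle 1, vehicle 2; vehicle 1, vehicle 2; its 3, vehicle 3) and 4 to 9, 13 to 3567 and 43 to 473 for catechin (vehicle 1, its 2; vehicle 3, its 3; vehicle 1, its 1). Others ran from 136 to 7312, 7 to 2968 and 4 to 10 for gallic acid (its 1, its 2; vehicle 1, its 3; vehicle 1, its 3) and 222 to 368, 5 to 7 and 17 to 4641 for hederagenin (its 3, its 1; vehicle 1, vehicle 2; vehicle 1, its 3). Then came 445 to 544, 28 to 53 and 12 to 23 for oleanolic acid (vehicle 1, its 1; vehicle 1, its 3; vehicle 1, its 3) and 11 to 34, 8 to 50 and 11 to 17 for paeoniflorin (vehicle 1, its 2; vehicle 3, its 3; vehicle 3, its 3). The span was 3 to 355, 3 to 9 and 3 to 375 for paeonol (vehicle 1, its 1; vehicle 1, its 3; vehicle 1, its 3). Next were 0 to 1 for paeoniflorin against albiflorin 10 µM (albiflorin 1, paeoniflorin 2), 56 to 7130 for gallic acid against benzoic acid 10 µM (gallic acid 1, gallic acid 2), 21 to 1878 for gallic acid 10 against 0.4 µM (10 µM 1, 10 µM 2) and 96 to 484 for hederagenin 10 against 0.4 µM (0.4 µM 2, 0.4 µM 3). Also seen were 0 to 2006 for hederagenin against oleanolic acid 0.4 µM (hederagenin 1, hederagenin 3), 0 to 2 for hederagenin against oleanolic acid 10 µM (hederagenin 2, hederagenin 1) and 278 to 343 for oleanolic acid 10 against 0.4 µM (10 µM 3, 10 µM 1).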

Other observations

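Of the tests below, that of iron was chosen only after the result was seen.

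The hypoxia marker CA9, followed after its values were seen, was at 2.83, 2.52 and 2.14 CPM with water extract at 20, 100 and 500 µg/mL and at 2.48, 3.92 and 57.5 CPM with ethanol extract, against 2.19 in vehicle.

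TFRC, whose transcript is stabilized when iron is low, was at 256, 266 and 317 CPM with rising doses of water extract and 255, 357 and 484 CPM with ethanol extract, against 219 in vehicle. If treated cells held less iron, SLC11A2, regulated in the same way, would rise with it. Both passed the test upwards in water extract 500, ethanol extract 100 and ethanol extract 500 µg/mL against vehicle, 6 of 6 cases. The 3 cases of TFRC restate what was seen, and only the 3 of SLC11A2 were able to fail, so less iron stays open, as do other regulators of both genes.

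Endoplasmic reticulum chaperones were higher with ethanol than water extract at 100 µg/mL and with gallic acid at 10 µM. If gallic acid or galloyl compounds carried the difference, gallic acid would resemble it most among the ingredients. Changes of gallic acid between 10 and 0.4 µM correlated with it across genes at r = 0.068, the highest of the 8 (the other 7 lay between -0.053 and 0.056) but below the bound of 0.1 set for it. Over genes of at least 10 CPM r was 0.146, and 16 genes were higher in both and 15 lower in both, where independent lists would share 0.544 and 0.37, with 1 in opposite directions. As the bound was set for all tested genes, the question stays open.

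The ATF4 list rose with oleanolic acid and hederagenin at 10 µM and ethanol extract at 500 µg/mL. If triterpenes carried the change of the extract, their changes with dose would resemble it. The highest correlation across genes was r = 0.113, for oleanolic acid, against at most 0.040 for the other 6 ingredients and below the bound of 0.2 set for it. For hederagenin r was 0.072, and over genes of at least 10 CPM the values were 0.179 and 0.176. With oleanolic acid 164 genes were higher in both and 108 lower (87.7 and 63.1 for independent lists, 97 in opposite directions), with hederagenin 75 and 43 (39.2 and 25.4, 48 opposite), so this stays open too.

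With 3 libraries against 3 there are 10 splits, so the share of splits with as many genes cannot fall under 0.05. With only the 2 groups in the fit, the real count and the highest of the other splits were 2470 and 1, 1400 and 1, 803 and 1 (water extract 500, 100, 20 µg/mL), 11257 and 0, 2116 and 0, 108 and 1 (ethanol extract 500, 100, 20 µg/mL), 11138 and 0, 403 and 3 (ethanol against water extract 500, 100 µg/mL) and 336 and 2, 11012 and 0 (water and ethanol extract 500 against 20 µg/mL), where 1 of 10 splits, the real one, gave as many. Among the ingredients the same held in 19 comparisons, with real counts of 1 (paeoniflorin against albiflorin 10 µM) to 6052 (catechin 0.4 µM) and at most 4 genes in any other split. As many genes came from 5 of 10 splits for albiflorin 10 against 0.4 µM (1 and 7) and 2 of 10 splits for hederagenin 10 against 0.4 µM (4 and 46). With a real count of 0, all 10 splits gave as many, and the highest other was 431 (ethanol against water extract 20 µg/mL), 6 (benzoic acid 10 against 0.4 µM), 2 (gallic acid 10 against 0.4 µM), 28 (paeoniflorin 10 against 0.4 µM), 209 (hederagenin against oleanolic acid 10 µM) and 3 (hederagenin against oleanolic acid 2 µM), and 0 or 1 in the other 15 comparisons. The split of ethanol extract replicate 1 with water extract replicates 1 and 2 at 20 µg/mL (431 genes), that of hederagenin replicate 1 with oleanolic acid replicates 1 and 2 at 10 µM (209), that of hederagenin 10 µM replicates 1 and 2 with 0.4 µM replicate 3 (46) and that of paeoniflorin 10 µM replicates 1 and 3 with 0.4 µM replicate 2 (28) called more genes than the real split (0, 0, 4 and 0). Each is the highest of the other splits of its comparison, and they point to a structure of the samples. Looked at afterwards, each of the 4 parts its libraries by mitochondrial share (up to 12.1 and from 13.1%, up to 7.61 and from 7.73%, up to 2.54 and from 7.61%, up to 9.81 and from 11.8%), and whether that share goes with the genes called was not tested.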
